A study of Mus musculus with 10 samples.

How the data were processed

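The series holds 10 RNA-seq libraries from 5 mouse small cell lung cancer (SCLC) cell lines, G4314, G9351, G9488, G9529 and G9577. Per the labels, the lines came from tumours of mice with altered Rb and p53 genes that also carry a MYCN transgene under a tetracycline-responsive promoter and the doxycycline-dependent activator rtTA. Each line gave 1 library with doxycycline in the medium (MYCN on) and 1 library after 4 days without it (MYCN off). Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was selected on oligo-dT beads, and libraries were made with the NEBNext Ultra kit, which does not mark strand. No spike-in RNA is named in the labels, so all levels are relative to the total of each library.

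Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 1.8.4 and aligned with STAR 2.5.2a to the mouse genome build mm9. Per the file headers, the deposited values are raw counts of reads per gene, made with featureCounts 1.6.0 from the UCSC iGenomes gene models for mm9, 1 file per library and without strand. The recorded command line has no option for reads that map to several places or overlap several genes, so such reads were not counted. Genes with near-identical copies elsewhere, such as ribosomal protein genes, Gapdh and the pair Mycn and Mycs, are therefore counted only in part. The files list 24391 genes by symbol, with no gene of the mitochondrial chromosome. Reads counted for Mycn cannot be assigned to the transgene or to the mouse gene, and the species of the transgene is not given in the sources used here. Reads of a human transgene may map to the mouse gene only in part, so the level and fold of Mycn may not measure the transgene in full. Coordinates are those of the files, in mm9 and counted from 1.

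The total count per library ran from 9586465 to 11960074. Genes with low counts were removed with edgeR's filterByExpr (minimum count 10), which left 12835 genes. These held between 93.9% and 99.9% of the counts of each library. The lowest share was in the MYCN-off library of G9577, because genes expressed in that line alone do not pass the filter. Counts were scaled with TMM factors. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with the cell line as a block and doxycycline as the tested term, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The fit had 4 residual degrees of freedom per gene and a biological coefficient of variation of 28.5%. An adjusted p given for a gene comes from this test unless another fit is named beside it. Log2 changes are MYCN on minus MYCN off, and their standard errors (SE) are the log2 change divided by the square root of F. Levels are TMM-scaled CPM, as mean ± SD over the 5 lines. Changes of single lines are differences of log2 CPM with a prior count of 2. The p-values rest on 5 lines with 1 culture for each line and condition, and nothing in the labels says whether the cultures were repeated.

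The design, the alternatives, 29 gene lists and the rule for named genes were fixed before the data were examined. The rule named a few genes in any case, among them Mycn, Myc, Mycl, Rb1, Trp53, Usp7 and Neurod1. It then took the 12 largest rises and the 12 largest falls among genes past the threshold with a mean CPM of at least 5 and the same sign in all 5 lines, without symbols of unnamed transcripts. Last, it took the up to 4 members with the smallest p from each list with a member past the threshold. Together it named 129 genes, and the text prints those that carry each comparison. Any other list member printed was chosen after its values were seen. Lists with at least 5 genes tested were tested with limma's camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 26 lists. Camera with a correlation estimated for each list, and fry, were alternatives.

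The lines pair the libraries by the labels, and this was checked. The deviations of the on and the off library of a line from their group means correlated across genes with r between 0.721 and 0.873, and no correlation with another line exceeded 0.273. No library was a copy of another. In simulated counts with the same design, run on 12657 genes, the test recovered 4.48% of genes changed 1.5-fold, 41.8% of those changed 2-fold and 93.9% of those changed 4-fold. It called 4 of 12457 unchanged genes. Only 67, 67 and 66 genes were changed at these folds, which makes the adjustment stricter than in data where many genes change. Alternatives were a fit without the line block, DESeq2 1.42.0, limma-voom, RLE scaling, library size alone, other filters on low counts, a test against a fold of 1.5, and each line left out in turn. All libraries name the same sequencing run in the file headers, so no batch was modelled.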

Results

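RNA was sequenced from 5 mouse SCLC cell lines, a neuroendocrine lung tumour type, each grown with doxycycline to keep a MYCN transgene on and without doxycycline for 4 days to turn it off. The 5 libraries with MYCN on held 9586465 to 11960074 counts, and the 5 with MYCN off held 9928420 to 11123998. Between 15250 and 17686 genes had at least 1 count in a library. The comparison asks which genes depend on MYCN in these lines. The series links MYCN to chemoresistance and to the deubiquitinase USP7, so lists for drug response and ubiquitin factors were included. No culture had doxycycline without the transgene, so effects of the drug itself are part of every difference below.

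Mycn, the targeted oncogene (mm9 chromosome 12, 12942899 to 12948642, minus strand), rose in all 5 lines with doxycycline, from 118 ± 66.5 to 737 ± 212 CPM (SD, n = 5 lines). Its fitted log2 change was 2.86 (SE 0.38), or 7.28-fold, with an adjusted p of 0.00421 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The smallest change was 1.61 in G4314 and the largest 4.16 in G9351. Transcript remained without doxycycline, at 29.5 CPM in G9351 and up to 194 CPM in G9488 before scaling. If the transgene is human, which the sources used here do not say, these counts may hold only part of its transcript, and the levels and the fold may not measure it in full. Mycs, an intronless near-copy of Mycn on chromosome X, rose 7.30-fold, but its counts were 3.68% to 5.01% of those of Mycn and cannot be separated from it with certainty. Myc (chromosome 15, 61816896 to 61821916, plus strand), the related oncogene, moved the other way, 6.22-fold lower with MYCN on (log2 change -2.64, SE 0.30, adjusted p = 0.00339) and lower in 5 of 5 lines. Mycl, the remaining family member, had a log2 change of 0.51 (SE 0.41, adjusted p = 0.358).

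Rb1 (chromosome 14, 73595309 to 73725598, minus strand), the tumour suppressor altered in these mice, was still counted in every library and fell to 104 ± 61.5 CPM with MYCN on from 190 ± 114 CPM (SD, n = 5 lines; log2 change -0.86, SE 0.15, adjusted p = 0.00885). Trp53 (chromosome 11, 69393861 to 69405375, plus strand) stood at 14.6 ± 2.11 CPM with MYCN on and 14 ± 3.14 CPM with MYCN off (SD, n = 5; log2 change 0.08, SE 0.23, adjusted p = 0.818). Counts per gene do not resolve deleted exons, so these levels do not check the genotype.

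**Figure D1:**
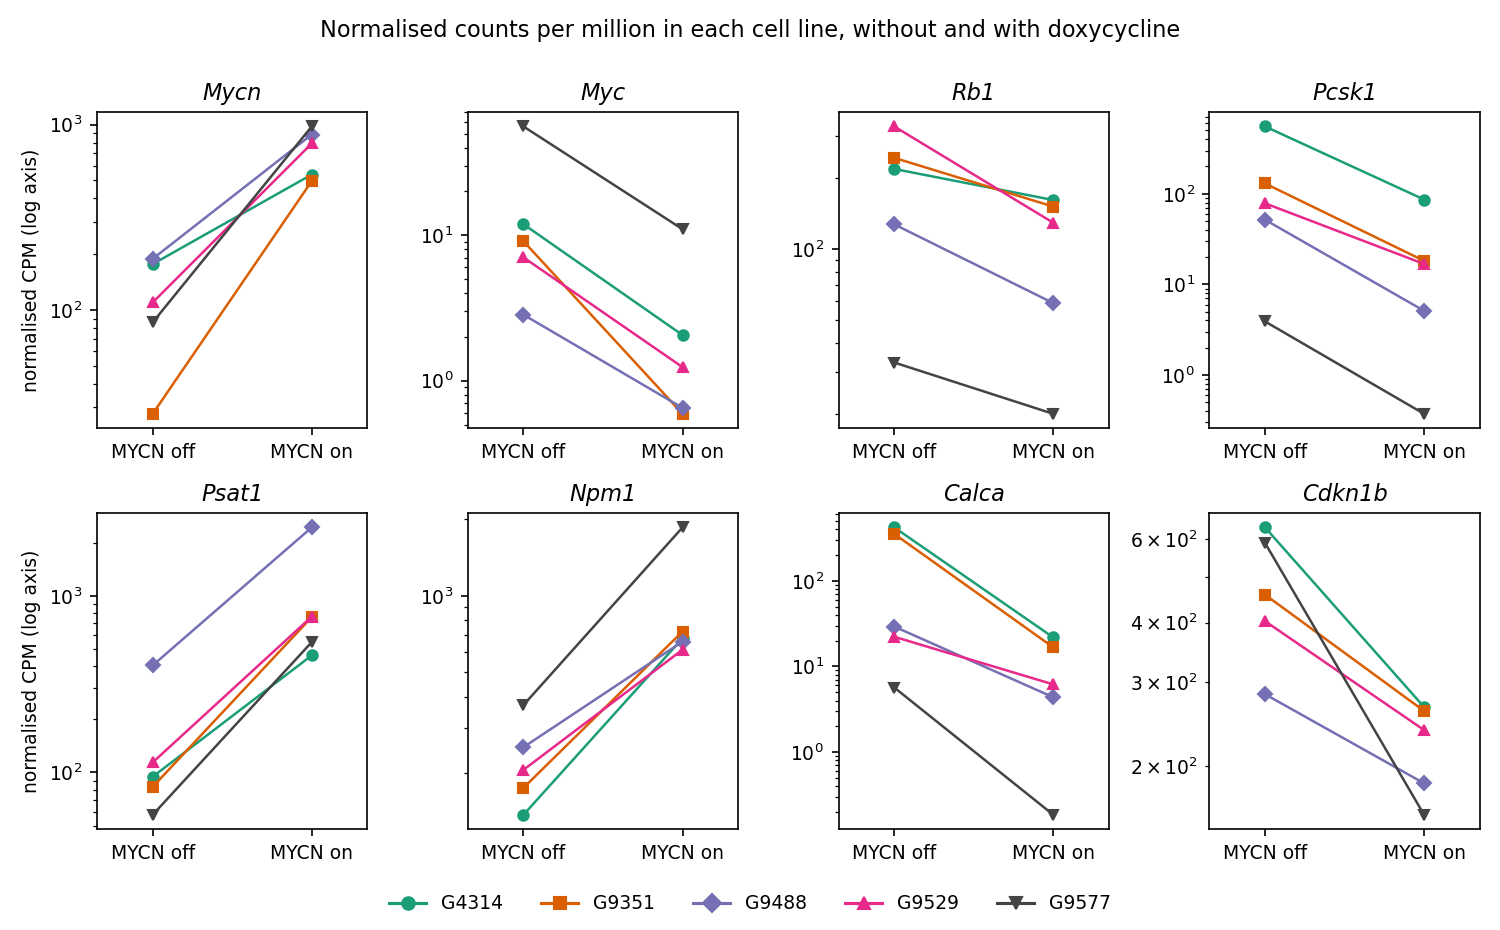
TMM-scaled CPM of 8 genes on log axes, with MYCN off on the left and MYCN on on the right of each panel, 1 line and symbol for each of the 5 cell lines. Mycn, Psat1 and Npm1 were higher with MYCN on in all 5 lines, and Myc, Rb1, Pcsk1, Calca and Cdkn1b were lower in all 5.

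Across the transcriptome, 3973 of 12835 genes tested (31.0%) changed, 1969 of them higher and 2004 lower with MYCN on, and 3734 of them had the same sign in all 5 lines. At least 2-fold changes were seen for 761 genes higher and 1108 lower. Among genes that the naming rule admits, the largest rise was that of Cth, which makes cysteine from cystathionine, at 24.8-fold (log2 change 4.63, SE 0.61, adjusted p = 0.00421). Bcat1, the cytosolic transaminase of branched-chain amino acids, rose 15.1-fold (3.92, SE 0.59, adjusted p = 0.00544). They were followed by the secreted factors Adm2 (12.1-fold) and Fgf21 (11.98-fold), hexokinase 2 (Hk2, 11.2-fold), deoxycytidylate deaminase (Dctd, 9.76-fold), the serotonin receptor subunit Htr3a (8.22-fold), Podxl (7.27-fold) and the translation repressor Eif4ebp1 (7.12-fold). Atg9b, which shares exon bases with Nos3, rose 7.38-fold. Adm2, Fgf21 and Eif4ebp1 lost their calls when G9351 was left out (adjusted p = 0.0965, 0.0703 and 0.0796), and again without G9529 (0.0927, 0.0572 and 0.0504). Adm2 and Eif4ebp1 lost them without G9488 too (0.0767 and 0.0564). Some of these folds moved with single lines: that of Adm2 was 7.38 without G9529, that of Fgf21 22.5 without G4314 and 7.78 without G9488, and that of Cth 38.1 without G9577. Adm2 was at 56 counts in both libraries of G4314, with a change of 0.11 there.

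Among the falls, Car8, a carbonic anhydrase-related protein, was 44.0-fold lower with MYCN on (log2 change -5.46, SE 0.57, adjusted p = 0.003), from 24.1 ± 43.3 to 0.389 ± 0.606 CPM (SD, n = 5 lines). Aldh1a3, a retinaldehyde dehydrogenase, was 30.4-fold lower, the thyroid hormone carrier Ttr 23.4-fold, Reps2 18.4-fold, Ankrd35 17.4-fold and the selenium carrier Sepp1 16.1-fold. B3galt2 (15.8-fold), Xdh (12.95-fold), Insrr (12.6-fold), the interleukin-1 receptor antagonist Il1rn (12.6-fold), the surface protein Cd200 (11.4-fold) and the calcitonin gene Calca (11.2-fold) completed the set, each lower in all 5 lines. In single lines some of these signs rest on a few counts. Il1rn went from 1 count to 0 in G9351, and B3galt2 from 2 to 0 and Insrr from 3 to 0 in G9577. With MYCN off, Xdh had 1375 counts in G9577 but 5 to 14 in the other lines. Car8 was 27.4-fold lower without G4314, Aldh1a3 48.4-fold without G9351 and 20-fold without G9577, and B3galt2 9.99-fold without G9351, all still called.

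Without the line block the test called 274 genes, 215 higher and 59 lower, all among the 3973 and in the same direction, and most genes named here then missed the threshold. The folds that moved by over 1.5 times in that fit were those of Bcat1 (9.93), Adm2 (7.67) and Dctd (6.35) among the rises printed, and of Xdh (31.2), Calca (16.8) and S100a4 (1.58) among the falls. Leaving out G4314 left 1768 genes called and leaving out G9351 left 1729. Of the 26 gene lists tested, camera called 16 with its preset correlation, 12 higher and 4 lower, but 0 with an estimated correlation, where 5 had an unadjusted p below 0.05 and the smallest adjusted p was 0.173. Fry called 15. Of the 16 splits of the libraries that part all 5 lines, 5 others gave at least as many list calls with the preset correlation. All 15 others, not these 5 alone, set on against off the same way in most lines. None is free of the real difference, so their list counts cannot show what chance alone gives. The counts of list members below rest on the tests of single genes. There the highest of the other 15 splits called 0 genes, but each of them turns the real difference round in some lines. The fit takes this as error, so their 0 does not bear on the member counts.

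Genes of the ribosome and its assembly rose together. Of 40 genes of ribosome biogenesis and the nucleolus, 38 rose and 0 fell (39 adjusted over the list alone), with a median log2 change of 1.55. Polr1b, a subunit of RNA polymerase I, rose 4.21-fold (SE 0.16 on the log2 scale), Npm1, the nucleolar chaperone nucleophosmin, 3.81-fold (SE 0.18), and Rrs1 3.001-fold (SE 0.14), each with an adjusted p of 0.00265. Gnl3, the nucleolar GTPase nucleostemin, rose 3.76-fold and shares exon bases with Glt8d1. The list call was lost with an estimated correlation (adjusted p = 0.373 with an estimated correlation). Of 74 cytosolic ribosomal protein genes, 68 rose and 0 fell (72 adjusted over the list alone), with a median of 1.19 (adjusted p = 0.184 with an estimated correlation). The summed CPM of the list was higher with MYCN on in each line, 11100 against 4460 in G4314 and 14100 against 7140 in G9577. All 27 translation factor genes tested rose (27 adjusted over the list alone; median 0.91; adjusted p = 0.173 with an estimated correlation), among them the poly(A)-binding proteins Pabpc4 (4.22-fold) and Pabpc1 (2.37-fold) and the initiation factor subunit Eif3i (2.22-fold). Because reads shared with pseudogene copies were not counted, levels of single ribosomal protein genes are uncertain.

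**Figure D2:**
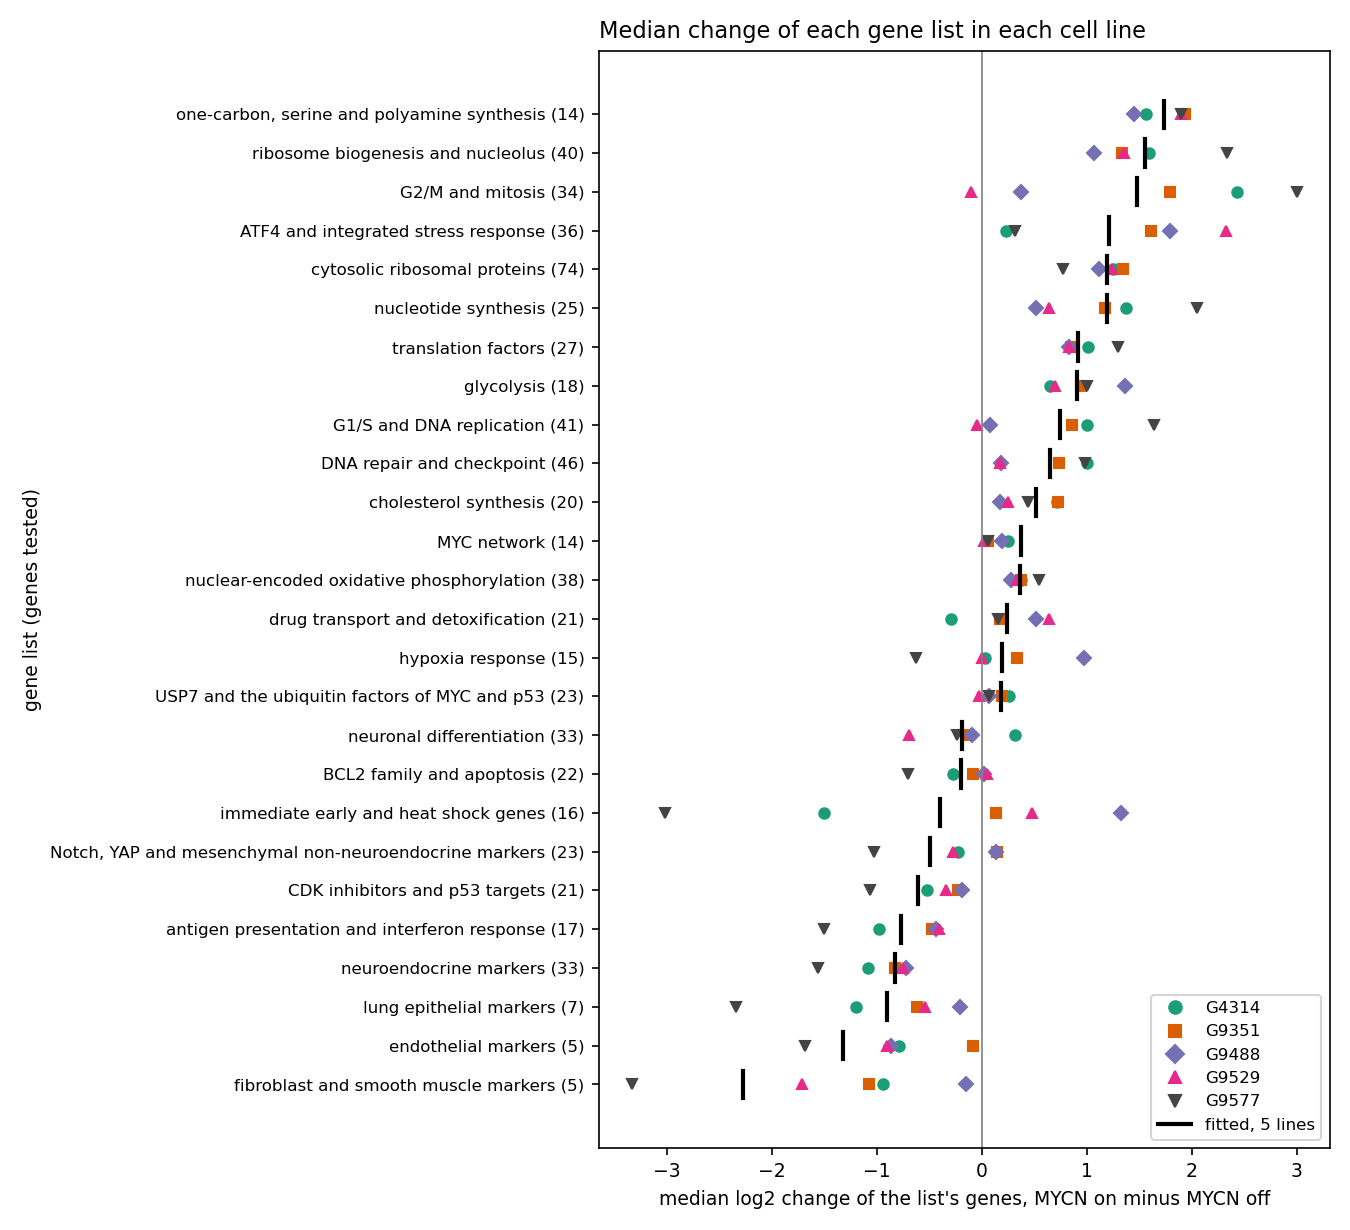
Median log2 change, MYCN on minus MYCN off, of the genes of each of 26 lists. Symbols are the 5 cell lines, black bars the median of the fitted changes, and the number of genes tested is in brackets. Lists of the ribosome, of translation and of one-carbon metabolism lie above 0 in all 5 lines, with medians of 1.55, 1.19, 0.91 and 1.73, while the mitosis list runs from -0.11 in G9529 to 3.0 in G9577.

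Biosynthetic enzymes were higher with MYCN on. In one-carbon, serine and polyamine synthesis 11 of 14 genes rose and 0 fell (12 adjusted over the list alone; median 1.73; adjusted p = 0.173 with an estimated correlation). The serine synthesis enzymes Psat1 and Phgdh rose 7.03-fold (SE 0.18 on the log2 scale) and 6.69-fold (SE 0.26), the mitochondrial folate enzyme Mthfd1l 3.91-fold, and Odc1, which opens polyamine synthesis, 3.17-fold. In nucleotide synthesis 18 of 25 genes rose and 0 fell (23 adjusted over the list alone; median 1.19; adjusted p = 0.391 with an estimated correlation). Cad, which starts pyrimidine synthesis, rose 4.56-fold, and the purine enzymes Prps1 and Atic rose 3.01-fold and 2.90-fold. Without G4314 the count was 11. Of 18 glycolysis genes 11 rose and 1, Hk1, fell (12 and 1 adjusted over the list alone; median 0.91; adjusted p = 0.184 with an estimated correlation). Besides Hk2, the lactate transporter Slc16a1 rose 4.85-fold and lactate dehydrogenase Ldha 4.04-fold. Gapdh rose 2.39-fold, from 13.97 ± 3.88 CPM (SD, n = 5 lines), a level that reflects only reads not shared with its pseudogenes. Hk1 lost its call without G4314, G9351 or G9488.

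Changes were smaller in the mitochondrial and sterol lists. Of 38 nuclear genes of oxidative phosphorylation 16 rose and 0 fell (16 adjusted over the list alone; median 0.36; adjusted p = 0.184 with an estimated correlation), for example Cyc1 (1.82-fold). These calls rest on small changes and dropped to 2 without G4314, 1 without G9351, 10 without G9488, 8 without G9529 and 9 with no filter on low counts. Of 20 cholesterol synthesis genes 8 rose and 1, Pmvk, fell (8 and 1 adjusted over the list alone; median 0.52; adjusted p = 0.391 with an estimated correlation). Fdps rose 2.11-fold. The count of rises was 3 without G4314, 3 without G9351 (median 0.307) and 5 without G9529, and Pmvk lost its call with each line left out and with no filter on low counts.

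Targets of ATF4, the transcription factor of the amino acid response, were higher, unevenly among lines. Of 36 genes 17 rose and 0 fell (17 adjusted over the list alone; median 1.21; adjusted p = 0.391 with an estimated correlation). Beside Cth, Psat1 and Phgdh, the glycyl-tRNA synthetase Gars rose 3.02-fold (SE 0.13 on the log2 scale, adjusted p = 0.00265) and the proline synthesis enzyme Aldh18a1 4.17-fold (SE 0.19). Of its stress genes only Fgf21 passed: Ddit3 had a log2 change of -0.08 (SE 0.43, adjusted p = 0.894) and Trib3 one of 1.94 (SE 0.93, adjusted p = 0.144). The median of the list was 0.23 in G4314 and 0.32 in G9577 against 1.61 in G9351, 1.79 in G9488 and 2.32 in G9529. The count of rises was 10 without G9351, but 25 without G9577 and 23 with DESeq2.

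Mitotic genes were higher in some lines. Of 34 genes of G2/M and mitosis 15 rose and 0 fell, against 32 adjusted over the list alone, with a median log2 change of 1.48 (adjusted p = 0.431 with an estimated correlation). The spindle checkpoint kinases Bub1b and Bub1 rose 4.08-fold (SE 0.49 on the log2 scale) and 4.15-fold (SE 0.57), and the kinase Aurkb 3.79-fold (SE 0.55). The list median was 2.43 in G4314, 1.79 in G9351 and 3.0 in G9577, but 0.37 in G9488 and -0.11 in G9529. The count was 4 without G9577 and 31 without G9529. In edgeR it was 0 without G4314 and 0 without G9351, where 8 and 14 members had an unadjusted p below 0.05, so Bub1b, Bub1 and Aurkb lost their calls there. It was 8 with RLE scaling or library size alone, 23 with no filter on low counts, and 32 with DESeq2. Of 41 genes of G1/S and DNA replication 11 rose and 0 fell (11 adjusted over the list alone; median 0.74; adjusted p = 0.435 with an estimated correlation), including the helicase subunit Mcm7 (1.84-fold), and 1 was called without G4314, 1 without G9351 and 18 with DESeq2. Its median was 1.004 in G4314, 0.86 in G9351 and 1.64 in G9577, but 0.07 in G9488 and -0.05 in G9529, and the fitted median was 0.458 without G9577. Of 46 DNA repair and checkpoint genes 21 rose and 0 fell (23 adjusted over the list alone; median 0.65; adjusted p = 0.391 with an estimated correlation), among them the checkpoint kinases Atr (1.92-fold) and Atm (1.75-fold), the end-joining factor Xrcc5 (1.89-fold) and Tdp1 (2.12-fold), which repairs topoisomerase 1 adducts. That count was 5 without G4314 and 5 without G9351. Atr shares exon bases with 1700065D16Rik.

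Of 21 CDK inhibitors and p53 targets 6 fell and 1 rose (6 and 1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.0514; 0.391 with an estimated correlation). Fry called it, as lower (fry adjusted p = 0.0312). Cdkn1b, which encodes the inhibitor p27, fell to 222 ± 48.1 CPM from 473 ± 142 CPM (SD, n = 5 lines; log2 change -1.06, SE 0.20, adjusted p = 0.00998). Perp was 2.25-fold lower, and the exonuclease gene Aen rose 2.99-fold. The falls numbered 2 without G4314, 3 without G9351, 2 without G9488 and 10 with DESeq2, and without G9577 there were 3 rises and 8 falls.

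Neuroendocrine genes were lower with MYCN on. Of 33 markers 21 fell and 2, Syt4 and Grp, rose (21 and 2 adjusted over the list alone; median -0.83; adjusted p = 0.373 with an estimated correlation). Calca was 11.2-fold lower, the prohormone convertase Pcsk1 6.98-fold (SE 0.20 on the log2 scale, adjusted p = 0.00265), and the granin Chga had a log2 change of -1.87 (SE 0.31, adjusted p = 0.00694). The synaptic vesicle genes Sv2a and Rab3c were 2.24-fold and 2.16-fold lower. Insm1, a neuroendocrine transcription factor, had a log2 change of 0.08 (SE 0.16, adjusted p = 0.729). The count of falls was 12 without G4314, and the rises numbered 1 without G4314, G9351 or G9488.

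Among 33 neuronal differentiation genes 7 fell and 1 rose (6 and 0 adjusted over the list alone), with no list call (adjusted p = 0.333; 0.718 with an estimated correlation). Stmn2 was 3.27-fold lower, L1cam 2.01-fold and Map2 1.70-fold, and 4 members fell without G9351. The rises numbered 4 without G9577, 5 with DESeq2 and 2 with limma-voom, and the 1 rise lost its call without G4314, G9351 or G9529. Of the SCLC subtype regulators, Yap1 rose 1.68-fold (adjusted p = 0.0331, and also adjusted over the list alone) and Neurod1 had a log2 change of 0.38 (SE 0.26, adjusted p = 0.291). Yap1 missed the threshold in limma-voom (adjusted p = 0.0714) and without each line except G9577 (adjusted p between 0.0532 and 0.111). Of 23 Notch, YAP and mesenchymal markers 5 fell and 1, Yap1, rose (5 and 1 adjusted over the list alone), with no list call (adjusted p = 0.212; 0.536 with an estimated correlation). Epha2 was 2.55-fold and S100a4 2.46-fold lower, and the falls numbered 2 without G9351, 3 without G9488 and 8 with DESeq2 or limma-voom, while 2 rose without G9577.

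Usp7 (chromosome 16, 8688815 to 8738435, minus strand), the deubiquitinase of the series title, stood at 296 ± 93.2 CPM with MYCN on and 247 ± 92.3 CPM with MYCN off (SD, n = 5 lines; log2 change 0.27, SE 0.17, adjusted p = 0.245). Of 23 ubiquitin factors of MYC and p53, 5 rose and 0 fell, but 1 adjusted over the list alone, with no list call (adjusted p = 0.158; 0.431 with an estimated correlation). Usp36, a nucleolar deubiquitinase, rose 1.87-fold (adjusted p = 0.0123). The rises numbered 1 without G4314, 1 without G9351, 3 without G9529, 2 without G9577 and 3 with RLE scaling, and 1 member fell without G9577 and 2 with DESeq2. In the MYC network, which holds Mycn and Myc themselves, 2 of 14 genes rose, Mycn and Max, and 3 fell, Myc, Mxd1 and Mxd4 (3 and 3 adjusted over the list alone; camera adjusted p = 0.348; 0.435 with an estimated correlation). Max, the dimer partner, rose 1.71-fold (SE 0.11 on the log2 scale) and its alternative partner Mxd1, a transcriptional repressor, was 2.73-fold lower (SE 0.25).

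Genes of drug response moved both ways. Of 21 drug transport and detoxification genes 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.188; 0.431 with an estimated correlation), with 1 and 1 left without G4314. The efflux pump genes Abcc1 and Abcb1b rose 2.16-fold and 3.80-fold, while Abcc5 was 1.64-fold lower. Abcb1b stood at 14.5 ± 29.3 CPM with MYCN on (SD, n = 5 lines) and lost its call without G4314 (adjusted p = 0.0586). It was well above the floor only in G9577, with 204 counts with MYCN off and 718 with MYCN on. The other lines had 0 to 7 counts with MYCN off and 7 to 18 with MYCN on, so its fold is uncertain there. Of 22 genes of the BCL2 family and apoptosis 3 rose and 4 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.544; 0.725 with an estimated correlation). The pro-death genes Hrk and Bid rose 3.30-fold and 3.17-fold, and Bcl2l1, which encodes the survival protein BCL-XL, was 1.82-fold lower. The falls numbered 2 without G4314 and 2 without G9529.

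Antigen presentation and interferon genes were lower where they moved. Of 17 genes 3 fell and 0 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.0326, but 0.431 with an estimated correlation), led by Tapbp, which loads peptides onto MHC class I (3.15-fold lower, SE 0.28 on the log2 scale), and Mx1 (4.42-fold lower). The count was 1 without G4314 and 5 without G9577, and 5 to 7 with each other scaling, filter and tool tried. Outside G4314, Mx1 was near the floor, with 7 to 19 counts with MYCN off and 0 to 5 with MYCN on, so its fold is uncertain there. Of 15 hypoxia genes 2 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.18; 0.604 with an estimated correlation), and the glycolytic regulator Pfkfb3 rose 4.03-fold. Without G9577, 6 rose, but 1 without G4314, G9351, G9488 or G9529 and 1 with each other scaling or filter tried, and the fall lost its call without G9351 or G9488. Of 16 immediate early and heat shock genes 2 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.878; 0.951 with an estimated correlation), and Dusp6, a phosphatase induced by ERK signalling, was 5.45-fold lower. The median of that list was -1.50 in G4314 and -3.02 in G9577 but 1.32 in G9488. Both rises, Hspa8 and Hsph1, lost their calls without G4314, G9351, G9488 or G9529, and 1 rise was left with each other scaling or filter tried. With limma-voom 2 fell.

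Markers of other cell types were tested as well. Of the fibroblast and smooth muscle markers 5 passed the filter on low counts, and 3 fell (4 adjusted over the list alone; median -2.28; camera adjusted p = 0.0264, but 0.391 with an estimated correlation), among them Col5a1 (3.35-fold lower). The count was 1 without G4314, 1 without G9488 and 1 without G9529, and the median was -1.40 without G9577. Of 5 endothelial markers 3 fell and 1 rose (3 and 1 adjusted over the list alone; camera adjusted p = 0.224; 0.435 with an estimated correlation). Vwf was 4.39-fold lower, and 1 marker fell without G4314 and 1 without G9529. Of 7 lung epithelial markers 3 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.01, but 0.391 with an estimated correlation), led by Hopx (4.54-fold lower) and Foxj1 (2.90-fold lower), and 5 fell with DESeq2 or with no filter on low counts. Hopx went from 6 counts to 0 in G9488 and from 1 to 0 in G9529, so its fold is uncertain there. Of the immune markers 1 was tested and did not pass, and 1 fell with no filter on low counts. The summed fibroblast markers stood at 8560 CPM with MYCN off and 2330 CPM with MYCN on in G9577, against at most 37.3 CPM in the other lines. In the lines where these markers fell, neuroendocrine genes fell too, with list medians from -0.72 in G9488 to -1.56 in G9577. The fall in G9577 was from a low level, a summed 1640 CPM with MYCN off against 11600 CPM or more in the other lines.

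One line stood apart from the others. The first principal component of log2 CPM held 56.1% of the variance and set both G9577 libraries apart from the other 8, and the second held 17.3%. Chga was at 9.53 and 1.09 CPM (before scaling, MYCN off and on) in G9577 and at 298 CPM or more in the other lines. Vim, the mesenchymal intermediate filament, was at 3560 and 1470 CPM in G9577 and at most 0.48 CPM elsewhere, and Yap1 at 204 and 274 CPM against at most 24.2. Per-gene changes of 2 lines correlated across genes with Pearson's r between 0.398 (G9529 and G9577) and 0.742 (G4314 and G9351), and genes are not independent replicates. Without G9577, 4493 genes changed, 3659 of them shared with the 3973 and all of these in the same direction.

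**Figure D3:**
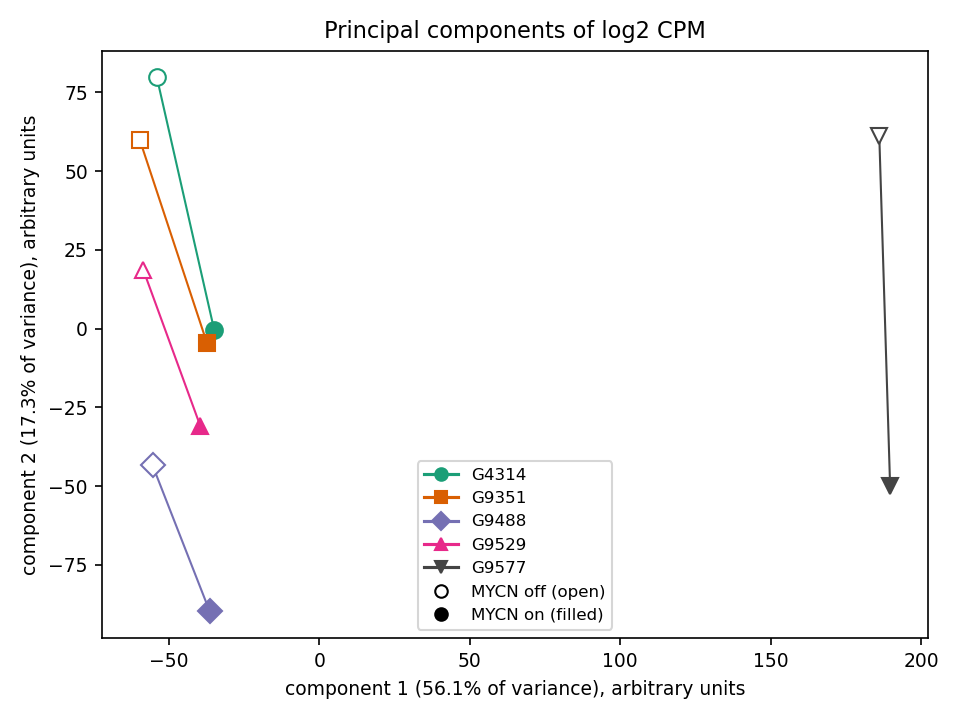
First and second principal components of log2 CPM, in arbitrary units, with 56.1% and 17.3% of the variance. Open symbols are MYCN off and filled symbols MYCN on, joined within each of the 5 lines, and both libraries of G9577 lie far from the other 8 on the first component.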

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

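The split counts, the test of the ATF4 genes and both tests on line G9577 were chosen in this form after results were seen, and the length tests before. The lines pair the libraries, so the real grouping was set against the other splits that part all 5 lines. There are 16 such splits with the real one, too few for a share under 0.05. The real grouping gave 3973 changed genes, and 1 of the 16 splits, the real one, gave as many, with 0 the highest of the others. For the list calls with the preset correlation, the real grouping gave 16, and 6 of the 16 splits, the real one included, gave as many, with a highest other of 19. All other splits that part the lines, these 5 included, set on against off the same way in most lines. They hold part of the real difference, so these list counts cannot show what chance alone gives. For the gene calls, the lines that they turn round add to the error of the fit. Their 0 was thus close to fixed in advance, and it does not show what chance alone gives either. Splits that keep both libraries of a line on one side differ, because the line block takes up part of the contrast. Among 100 splits drawn from 126, the highest of these gave 1340 genes, and it is the real contrast in G4314, G9351 and G9577.

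In groups of 5 values, 181 were searched for a library or line set far apart from the others relative to the range, and 10 were found, close to the 1 in 20 that chance gives. Line G9577 supplied 7 of them. Its MYCN-off library had the lowest TMM factor of its group, 0.8605, against 1.02 for the next. Myc was highest in G9577 in both conditions, at 55.9 CPM with MYCN off (next 11.9) and 11 CPM with MYCN on (next 2.06). The change of Mycl was 2.80 in G9577, with 0.26 the next. The change of Ifih1 was -2.43 there (next -0.98), that of Mxd1 -2.62 (next -1.26) and that of Cyc1 1.51 (next 0.80). Odc1 changed least in G4314, by 1.10 (next 1.75), Eef1g changed most in G4314, by 1.72 (next 1.47), and Gnl3 changed least in G9488, by 1.08 (next 1.97).

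Ribosomal protein and ribosome biogenesis genes were higher with MYCN on, by median log2 changes of 1.19 and 1.55, and since ribosomal protein transcripts are short, a bias toward short transcripts could raise them. Random lists of genes matched on exon length and mean expression argue against that as the whole cause for the ribosomal protein list. Of these, 0 of 10000 had a median as large, with a mean of 0.18 and a highest of 0.48. The match was incomplete, with a median of 864 exon bases against 717.5 in the list. Biogenesis genes are longer, with a median of 2510.5 exon bases, so a bias toward short transcripts bears less on them. For that list 0 of 10000 matched lists had a median as large, with a highest of 0.49. Across all genes the change correlated with exon length at a Spearman's rho of -0.13. In G9529 the medians of the mitosis and G1/S lists were -0.11 and -0.05 while those of the ribosomal protein and biogenesis lists were 1.24 and 1.36, so the rise there came without higher list medians for the cell cycle, whereas in G9577 the mitosis and biogenesis medians were the highest of the lines (3.0 and 2.33) and the ribosomal protein median the lowest (0.77). Growth itself was not measured, so faster growth stays open in part, and a direct effect of MYCN was not tested.

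ATF4 genes had medians of 1.61 or more in G9351, G9488 and G9529 and of 0.23 and 0.32 in G4314 and G9577, and stress from doxycycline itself is a candidate explanation. The 13 stress members tested had a median log2 change of 1.16, with medians of -0.59 in G4314 and -1.0 in G9577 but 2.72 in G9488. Their mean over lines was 1.06 (SE 0.79, n = 5 lines). The 20 members that make, carry or charge amino acids had a positive median in each line, from 0.67 in G4314 to 2.32 in G9529. Doxycycline and MYCN cannot be told apart for these genes, because no culture had one without the other.

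Line G9577 was low in neuroendocrine transcripts, with a summed list level of 1640 and 1040 CPM (MYCN off and on) against at least 7150 CPM in the other lines, and expressed mesenchymal ones. Mycn rose there by 3.50 on the log2 scale, to 876 CPM before scaling, the highest of the 5 lines. This argues against cells that lack the transgene in place of tumour cells. It does not bear on stromal cells of these mice, since by the labels the mice themselves carry the transgene and rtTA. A wrong label on 1 of its 2 libraries is argued against by the correlation of their deviations from the group means, 0.873, against at most -0.385 with any other line. A non-neuroendocrine state of the tumour cells, a mix of such cells with others, and stromal cells that carry the transgene stay open. No biological explanation was tested, since the labels give no such group.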

How the results depend on the processing

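The pairing by line decides most calls. Without the line block 274 genes were called (215 higher, 59 lower, a share higher of 78.5% against 49.6%), all shared with the blocked fit and in the same direction, 2840 had an unadjusted p below 0.05, and 2 lists were called lower. The lines differ widely, and the unblocked fit leaves that difference in the error. Of 129 named genes 99 then lost the call they had in the blocked fit. Against a fold of 1.5, 869 genes were called (427 higher, 442 lower), which is stricter by construction. With each line left out, 1729 (without G9351) to 4493 (without G9577) genes were called, 813 to 2244 higher and 916 to 2249 lower, with fewer samples in each fit. Why the single lines differ in this was not tested. With an estimated correlation 0 lists were called, 0 higher and 0 lower. The estimate was above the preset 0.01 for each list except the MYC network (-0.04). It was 0.94 for mitosis, 0.276 for ribosomal proteins and 0.0923 for one-carbon, serine and polyamine synthesis. A higher correlation makes camera stricter by construction, so a lost list call does not show that the list did not move. Counts under DESeq2 (5280), limma-voom (4467), RLE scaling (4023), library size alone (4012), no low-count filter (3940) and the CPM filter (4015) stayed within 1.5 times of 3973. No result changed sign while called. Leaving aside the fold test, 25 of the named genes kept their side of the threshold in all fits that tested them, and 89 in all but the unblocked one. In simulation of this comparison 4.48% of 1.5-fold changes were recovered, but only 67 genes were given that change. With so few changed genes the adjustment is stricter than with 3973 calls, so that share does not carry over to these data. With 4 residual degrees of freedom, genes not called may still have changed, as the range of 274 to 5280 calls over the alternatives allows.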

Other observations

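Gene families not described above were picked by their symbols, and their direction was predicted before they were tested. Mitochondrial ribosomal protein genes rose with MYCN on: 51 of 76 passed the test and 0 fell, with a median log2 change of 0.63, and Mrpl34 led with 1.24 (SE 0.13, adjusted p = 0.003). Chaperonin genes, which fold newly made proteins, had 10 of 11 members higher and 0 lower (median 1.06), among them Cct3 (1.37, SE 0.18) and Hspe1 (1.70, SE 0.23). Nuclear transport genes had 28 of 39 higher and 0 lower (median 0.78), with Ipo7 at 1.32 (SE 0.16). Of 36 proteasome subunit genes 27 rose and 0 fell (median 0.56), for example Psmd14 (0.93, SE 0.17). Of 14 hosts of small nucleolar RNAs 8 rose and 1 fell (median 0.87), and Gas5 rose by 1.28 (SE 0.12).

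Other families were lower. Of 31 lysosomal and V-ATPase genes 13 fell and 1 rose (median -0.50), among them the proton pump subunits Atp6v0d1 (-0.97, SE 0.15) and Atp6v0a1 (-1.01, SE 0.16). Of 78 ion channel genes 22 fell and 0 rose (median -0.68), including Scn1a (-1.13, SE 0.14), Cacna2d1 (-1.30, SE 0.16) and Kcnip2 (-2.00, SE 0.24). In each of the 5 lines all 7 families had a median on the predicted side of 0. Camera with the preset correlation called all 7 in the predicted direction, but none passed with an estimated correlation (adjusted p = 0.21 for each). The hypothesis that MYCN raises the machinery for making, folding and moving proteins and lowers that for excitability and lysosomes may hold in these lines, at the level of single genes. The list test does not carry this, since no family passed with an estimated correlation, and doxycycline itself stays an open explanation.

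Transcripts that mark sex separated the lines as a check of identity. Xist was at 1720 and 2290 CPM in G4314 and 1400 and 867 CPM in G9577 (MYCN off and on), and at most 2.72 CPM in the other lines, which had Ddx3y at 58.4 to 98.5 CPM. The on and off libraries of each line agree in both genes. The share of counts from Rn45s, the ribosomal RNA precursor left after selection of polyadenylated RNA, ran from 0.0867% to 0.566% of a library.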
